A study of Mus musculus with 6 samples.

How the data were processed

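RNA was measured by sequencing in the cortex of male C57BL/6J mice 14 days after stroke, in 3 libraries from animals given short-chain fatty acids (SCFA) in their drinking water and 3 libraries from salt-matched controls. Per the labels' protocols, the animals also received the antibiotics metronidazole, neomycin, ampicillin and vancomycin with 5% sucrose, and SCFA or the control salts were offered freely for 4 weeks from an age of 6 to 8 weeks. Total RNA came from snap-frozen cortex through RNeasy Mini columns, and libraries were made with a kit sold for human FFPE RNA (Ovation Human FFPE RNA-Seq), per the labels' protocols. Which hemisphere was taken, and how far from the lesion, is not given in the sources used here. The design text speaks of 3 mice per group, so each library was taken as 1 animal.

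The deposited values are raw counts of reads per RefSeq transcript, in 1 table of 34755 rows with a column for each of the 6 libraries. Per the submitters' processing notes, CASAVA 1.8.2 and featureCounts were used with the mouse build mm10, and the aligner, the strand setting and the treatment of reads shared by several transcripts are not given in the sources used here. Of the rows, 34424 (99.05%) were matched to a gene symbol through a RefSeq table of the assembly GRCm38.p6, the assembly also known as mm10, and rows of the same symbol were summed, which left 24553 genes and unmatched rows. Of protein-coding genes with 1 row, 61.3% had enough counts to be tested, against 34.3% of those with 2 or more rows, and 29.4% of the latter stood at 0 in all 6 libraries against 17.1% of the former. A count that leaves out reads shared by isoforms would give such a pattern, so a count of 0 for a gene with several transcripts was not read as absence. Dlg4, for example, had 0 counts in all 6 libraries. Reads shared by near-identical paralogs, as in the trypsin, amylase and elastase families, are uncertain for the same reason, and without a known strand setting overlapping genes cannot be separated.

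Total counts ran from 9275252 to 13862756 per library. A single unmatched row took between 35.0% and 55.3% of the counts of each library, which left 5092272 to 7776672 counts for everything else. It stayed in the library sizes of the main test, and was removed with ribosomal and structural RNA genes in an alternative. That alternative was also to remove mitochondrial genes, of which the table held 0 rows by symbol. With the effective library sizes, 3 counts stood for 0.207 to 0.346 CPM. That floor of 3 counts per library was used wherever all 3 libraries of a group were at 0. Intervals on ratios of counts are exact 95% binomial intervals, and they and the floors cover counting error only.

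Genes were tested with edgeR 4.0.16 in R 4.3.3. The low-count filter filterByExpr (minimum count 10, minimum total 15) kept 11969 genes, TMM gave the scaling factors, and the quasi-likelihood F test compared the groups with no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, and the standard error of a log2 fold change was computed as its size divided by the square root of F. Gene lists were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, for lists with at least 4 tested genes, with Benjamini-Hochberg adjustment over the lists. Of 44 lists of cell-type markers, brain regions and functions, 43 were meant for this test and 39 had enough genes. The score of a list in a library is the mean log2 CPM of its members minus their mean over the 6 libraries, with a prior count of 2.

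The samples, groups, tests, gene lists, the alternatives (except for 2 given as added) and the rule for named genes were fixed before the data were examined. The rule takes per direction up to 12 genes past the threshold with a mean of at least 1 log2 CPM, no overlap between the groups and the largest change. Where fewer than 6 pass, those with the smallest p are added up to 6. It adds from each called list the 4 members with the smallest p and from each other list 2, and Ffar2, Ffar3, Hcar2, Slc16a1, Hdac1, Hdac2, Hdac3, Gfap, Aif1, Cx3cr1, Trem2, Cd68, Bdnf, Dlg4, Snap25 and Syp whatever their value. Predicted genes are passed over in the first parts. Lists of organ markers (exocrine pancreas, pancreatic islet, liver, intestine, skeletal muscle, salivary gland and kidney) were written after the gene results had been seen.

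The alternatives were DESeq2 size factors, upper-quartile scaling and total counts in place of TMM, no filter and a stricter filter (CPM above 1 in 3 libraries), DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, each library left out in turn, structural RNA removed, an adjusted p under 0.1, and for lists an estimated correlation, fry and a test on the DESeq2 statistics. The transcript rows without summing, and the comparison without the libraries control 2 and SCFA 2, were added after the data had been seen. The gene test was tested on simulated counts with 200 changed genes among 11470 tested. It recovered 33 of 70 genes changed 2-fold, 52 of 70 changed 4-fold and 57 of 60 changed 16-fold, with 11 false calls among 153. The changed genes were drawn from those above 1 log2 CPM. No simulated library stood apart as control 2 and SCFA 2 do in the data, so these rates need not hold for the real libraries. In a simulation of the list test, all 5 lists shifted by 0.5 on the log2 scale were called and 0 of 34 others. The simulated genes were independent of each other, so this gives no rate of false calls for lists whose genes vary together. No library was a copy of another, since the chi-square per degree of freedom between pairs lay between 12.28 and 141.5.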

Results

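The cortex of 6 mice was profiled 14 days after stroke, at an age of 15 weeks. Of these animals, 3 had received SCFA, the small organic acids that gut bacteria make from fibre, and 3 had received a salt-matched control. The comparison asks how SCFA treatment alters the transcriptome of the post-stroke cortex. Total counts were 10992306, 11397967 and 10393480 in controls 1 to 3 and 9275252, 11961316 and 13862756 in SCFA 1 to 3. A single row that could not be paired with a gene took 37.7%, 55.3% and 44.5% of the counts in controls 1 to 3, and 42.2%, 35.0% and 46.3% in SCFA 1 to 3. In each group a library stood apart from the others. Control 2 lay at 109.2 on the first principal component (50% of the variance), where the other 5 libraries lay between -25.77 and -17.74, and it had counts in 13600 rows against 15988 to 16941 in the others. SCFA 2 lay at 51.59 on the second component (15.3% of the variance), and the library with the next highest value, SCFA 3, lay at 9.537.

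With SCFA, 1 gene was higher and 9 were lower among 11969 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The higher gene was Laptm5, which encodes a lysosomal membrane protein of immune cells, on chromosome 4 from 130912890 to 130936148 (GRCm38). It measured 44.3 ± 10.6 CPM in controls and 109 ± 14.6 CPM with SCFA (SD, n = 3 each), a log2 fold change of 1.29 (SE 0.197, adjusted p = 0.0264). Each SCFA library lay above each control. The next 5 genes by p did not pass in edgeR. They were C1qb, a subunit of the complement starter C1q (log2 fold change 1.17, SE 0.236, adjusted p = 0.194), the astrocyte filament gene Gfap (0.95, SE 0.207, adjusted p = 0.346), the lysosomal protease genes Ctsc (1.22, SE 0.269) and Ctsd (1.003, SE 0.223), both with an adjusted p of 0.352, and the astrocyte glutamate transporter gene Slc1a3 (0.80, SE 0.179, adjusted p = 0.361). At an unadjusted p under 0.05 there were 356 genes higher and 334 lower, 690 in all where chance alone gives 598. Leaving out 1 library gave 164 to 477 higher and 218 to 382 lower, both lowest without SCFA 2. Total-count scaling gave 430 higher and 56 lower. Laptm5 did not pass without control 1, control 3, SCFA 1, SCFA 2 or SCFA 3, with adjusted p values from 0.0906 to 0.215, nor with limma-voom or total-count scaling (adjusted p = 0.0613 and 0.0905). C1qb, Gfap, Ctsc, Ctsd and Slc1a3 passed with DESeq2, which called 16 genes higher, and all of them but Ctsc passed without a filter on low counts, which gave 30. Calls without that filter carry little weight, since edgeR then gave Laptm5 an adjusted p of 7.82e-09 at nearly the same log2 fold change. The number of genes higher rose to 8 without control 2 and to 14 without control 2 and SCFA 2 together.

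**Figure D1:**
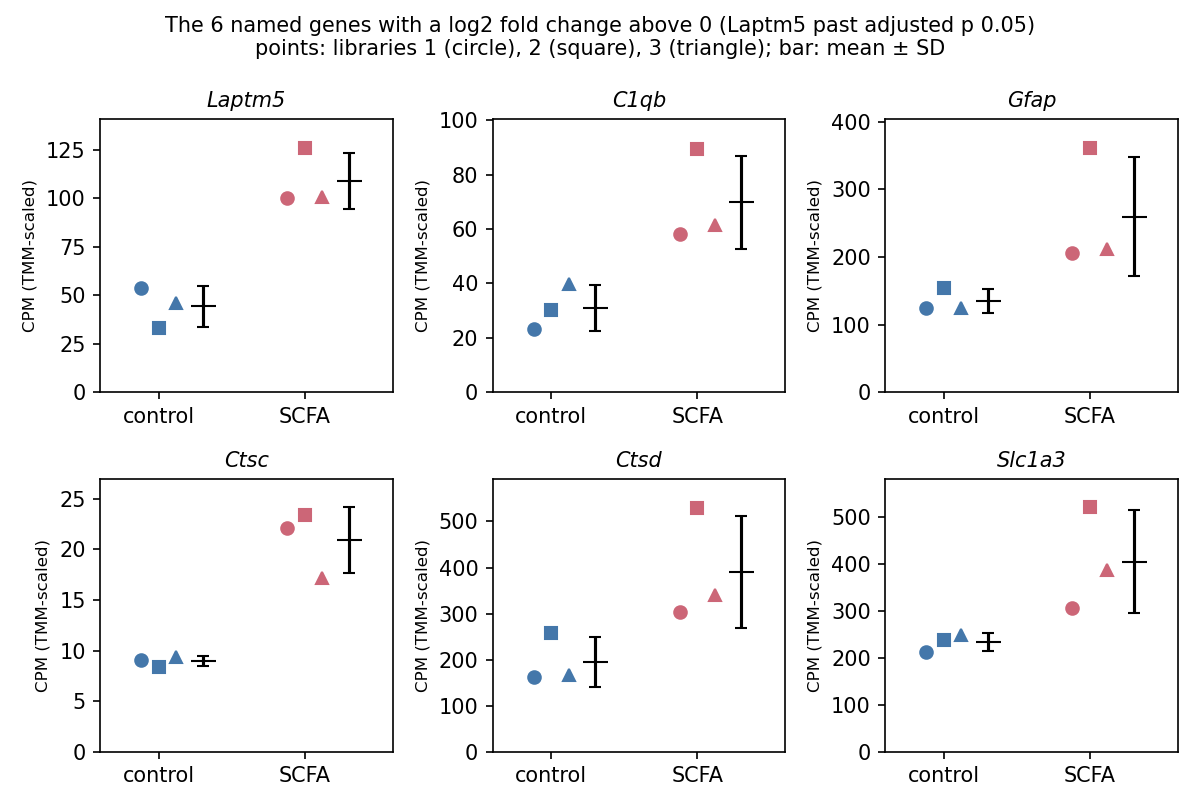
TMM-scaled CPM of 6 genes in each library, controls in blue and SCFA in red, with the mean and SD beside each group of 3. Laptm5 measured 44.3 ± 10.6 CPM in controls and 109 ± 14.6 CPM with SCFA, and it alone of the 6 had an adjusted p under 0.05.

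The 9 genes lower with SCFA all encode secreted products of the exocrine pancreas, the tissue that makes digestive enzymes. Amy2a5, a pancreatic amylase gene on chromosome 3 from 113249178 to 113258699, had 1237, 1726 and 105 counts in controls 1 to 3 and 2, 4 and 2 in SCFA 1 to 3. Its CPM was 464.2 times higher in controls (counting interval 235.3 to 1076, adjusted p = 0.0107). The elastase gene Cela2a (chromosome 4, 141814954 to 141826005) had 103, 179 and 29 counts in controls and 0 in each SCFA library, at least 42.9-fold lower. The trypsin gene Try5 and the carboxypeptidase gene Cpa1 were likewise at 0 with SCFA, at least 39.1-fold and 23.3-fold lower. The chymotrypsinogen gene Ctrb1 had 227 counts in controls and 1 with SCFA, a CPM ratio of 274.8 (interval 48.82 to 10900). Pnliprp1, a lipase-related gene, had 391 and 3 counts, a ratio of 157.8 (interval 53.59 to 768.4), and the lipase gene Pnlip had 601 and 6 (121.3, interval 55.38 to 331.7). The carboxypeptidase gene Cpb1 had 520 and 6 counts (104.9, interval 47.88 to 287.2). The trypsinogen-like gene 2210010C04Rik, outside the naming rule and named after its values were seen, had 213 and 2 counts (128.9, interval 35.25 to 1071). The size of these differences moved with single libraries. Without control 2 the ratio of Amy2a5 was 282 and that of Pnliprp1 79.5, and the bounds of Cela2a and Try5 were 22.7 and 24.9. The SCFA counts of Cpb1, Pnliprp1 and 2210010C04Rik all came from SCFA 1, and without it the genes were at least 76.5-fold, 64.1-fold and 31.0-fold lower. Those of Pnlip and Ctrb1 came from SCFA 3, without which the bounds were 75.9 and 27.6. Without SCFA 2 the ratios of these 5 genes lay between 64.3 and 168, and without SCFA 3 those of Cpb1, Pnliprp1 and 2210010C04Rik were 67.4, 101 and 82.8. Because trypsins, amylases and elastases have near-identical copies, the split of reads among their members is uncertain. The adjusted p of the genes with a log2 fold change below 0 that passed lay between 0.0107 and 0.0299. No gene in this direction passed without SCFA 1, SCFA 2 or SCFA 3 (edgeR, 0 genes lower each, with 382, 218 and 242 genes at an unadjusted p under 0.05), and 1 passed without control 1. With limma-voom 0 passed (384 at an unadjusted p under 0.05). With DESeq2 21 passed and Cpb1 did not (adjusted p = 0.184). With robust dispersion 8 passed, of which 7 were among these 9 and the other was Dmbt1, named after its values were seen, while Amy2a5 (adjusted p = 0.828) and Pnlip (adjusted p = 0.0518) did not. Over a wider list of 31 exocrine pancreas genes, written after these results were seen, controls held 8065 counts and SCFA libraries 190.

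**Figure D2:**
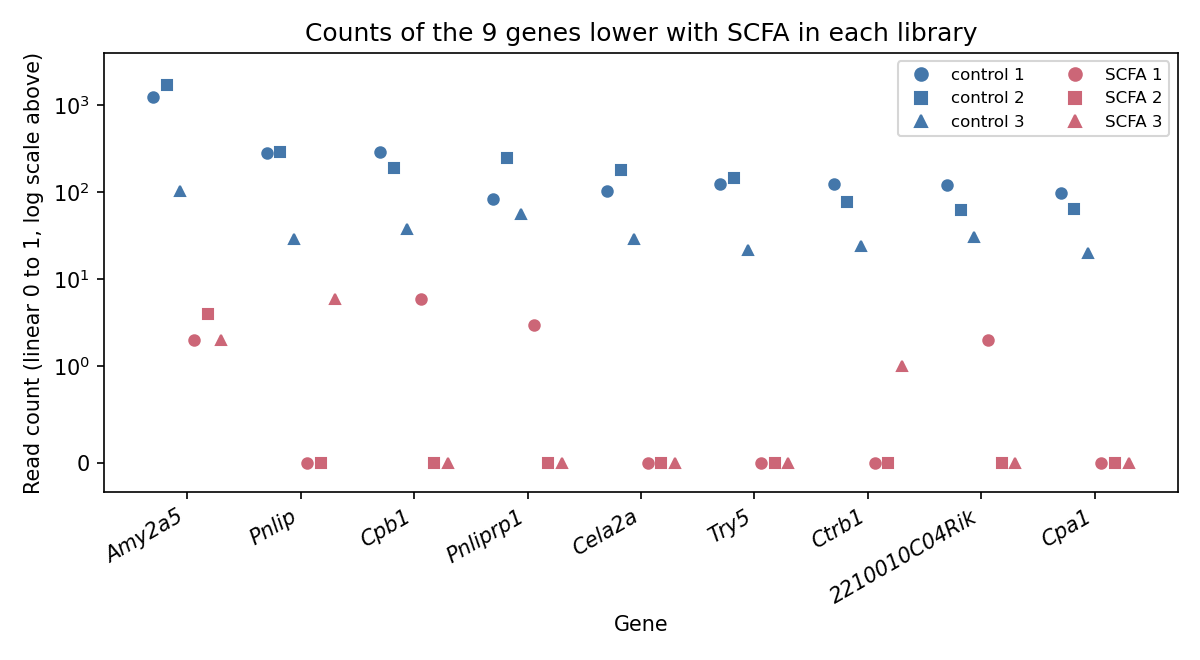
Read counts of the 9 genes lower with SCFA in each of the 6 libraries, on an axis that is linear from 0 to 1 and logarithmic above. Amy2a5 had 105 to 1726 counts in controls and 2 to 4 with SCFA, and Cela2a, Try5 and Cpa1 had 0 in each SCFA library.

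Microglia, complement and astrocyte lists rose together with SCFA (5 lists called by camera at its preset correlation). None of the 5 passed with an estimated correlation (adjusted p = 0.405 for each). The complement list, innate immune proteins that tag targets for removal, had a median log2 fold change of 1.03 over 10 measured genes (camera, adjusted p = 8.61e-12). No member passed the gene test over all genes, and 7 of 10 passed adjusted over the list alone. An adjustment over a list alone leaves out the genes outside it and the choice among the lists tested, here and below. C1qc had a log2 fold change of 1.01 (SE 0.230), C1qa of 1.05 (SE 0.256) and the complement receptor gene C3ar1 of 1.72 (SE 0.414). Genes of activated, phagocytic microglia, the resident macrophages of the brain, had a median of 0.76 over 14 genes (adjusted p = 3.51e-10), and 13 of them lay above 0. Of the 20 genes fixed for this list, Trem2, Clec7a, Spp1, Lgals3, Axl and Fabp5 had too few counts to be tested. Each of these has several transcript rows. Ctsd and the microglial signalling adaptor gene Tyrobp (0.96, SE 0.223) had the smallest p, and adjusted over the list alone 2 passed. Homeostatic microglia had a median of 0.51 over 13 genes (adjusted p = 1.82e-05), with P2ry13 at 1.19 (SE 0.343), and 2 passed adjusted over the list alone. Reactive astrocytes had a median of 0.66 over 11 genes (adjusted p = 1.92e-05), 4 of which passed adjusted over the list alone. Among them, the protease inhibitor gene Serpina3n measured 1.51 (SE 0.387) and Lcn2, a secreted iron-carrier protein gene, 2.53 (SE 0.739). Homeostatic astrocytes had a median of 0.50 over 13 genes (adjusted p = 2.17e-05), with Slc1a3 and Slc1a2 at 0.80 and 0.55, and 4 passed adjusted over the list alone. The score of each of these lists was highest in SCFA 2, at 1.09 for complement and 0.95 for activated microglia. For the astrocyte lists the groups overlapped, since control 2 scored 0.12 and SCFA 1 scored 0.07 in the reactive one, and control 3 scored -0.02 and SCFA 1 scored -0.05 in the homeostatic one. Without SCFA 2 the medians were 0.76, 0.54, 0.27, 0.55 and 0.25, in the order named, without control 2 they were 1.10, 1.19, 0.60, 1.01 and 0.39, and without both 0.84, 0.93, 0.30, 0.92 and 0.31.

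Rises were called in 4 further lists and falls in 3, and none of these 7 calls held with an estimated correlation or without SCFA 2. Endothelial genes had a median of 0.40 over 11 genes (adjusted p = 0.0196, or adjusted p = 0.497 with an estimated correlation), led by the glucose transporter gene Slc2a1 at 0.71 and Flt1 at 0.78. Control 2 scored -0.77 for this list and the other 5 libraries -0.09 to 0.32, and without control 2 the median was 0.21 and the call was lost (adjusted p = 0.111), while without SCFA 1 it was 0.23 and called. Oligodendrocyte precursors had a median of 0.39 over 10 genes (adjusted p = 0.0196, or adjusted p = 0.405 with an estimated correlation), with Gpr17 at 0.96 and Sox10 at 0.96. Control 2 scored -0.68 and the others -0.27 to 0.57, and the call was also lost without control 3 (adjusted p = 0.0789), while without control 1 the median was 0.62 and called. Cytokines and chemokines had a median of 0.58 over 10 genes (adjusted p = 0.0233, or adjusted p = 0.405 with an estimated correlation), where Cxcl16 measured 1.13, Tgfb1 0.89 and Il18 -0.96, and the call was also lost without control 1 (median 0.905, adjusted p = 0.0983) or control 3 (0.45, adjusted p = 0.114). The median rose to 0.88 without control 2 and to 0.94 without SCFA 1, both called, and without control 2 and SCFA 2 together it was 0.29 and called (adjusted p = 0.0451). Interferon-stimulated genes had a median of 0.38 over 14 genes (adjusted p = 0.0429, or adjusted p = 0.647 with an estimated correlation), with Rsad2 at 2.26, Irgm1 at 0.82, Ifit2 at 0.43 and Isg15 at -1.07. The groups overlapped in this list, where control 2 scored -0.91, control 3 scored 0.45 and SCFA 1 to 3 scored 0.37, 0.50 and -0.10. The median rose to 0.77 without control 3 (adjusted p = 0.00121), to 0.59 without SCFA 3 (adjusted p = 0.00199) and to 0.58 with limma-voom (adjusted p = 0.0348). Its call was also lost without control 1, control 2 or SCFA 1 (adjusted p = 0.33, 0.19 and 0.193), with total-count scaling, without a filter on low counts (adjusted p = 0.0589) and on the DESeq2 statistics (adjusted p = 0.155), and without control 2 and SCFA 2 together the median was 0.10. Cholesterol synthesis, with Insig1 at -0.56, had a median of -0.23 over 14 genes (adjusted p = 0.0196, or adjusted p = 0.497 with an estimated correlation). The nuclear-encoded respiratory chain had a median of -0.20 over 20 genes (adjusted p = 0.0321, or adjusted p = 0.528 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.12 over 20 genes (adjusted p = 0.0233, or adjusted p = 0.649 with an estimated correlation), which became 0.03 with total-count scaling, a scaling that moved the median of all genes from 0.01 to 0.18. No member of these 7 lists passed, over all genes or adjusted over the list alone. The scores of ribosomal proteins and of the respiratory chain lay at -0.45 and -0.35 in SCFA 2 and between 0.00 and 0.15 in the other 5 libraries, and without SCFA 2 their medians were 0.02 and -0.03. Both were called without SCFA 1, with medians of -0.18 and -0.30, and without SCFA 3, with -0.24 and -0.25. The calls of the 3 lower lists were also lost without control 2 and with total-count scaling, those of cholesterol synthesis and ribosomal proteins without control 3, that of the respiratory chain without control 1 and that of cholesterol synthesis without SCFA 1.

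**Figure D3:**
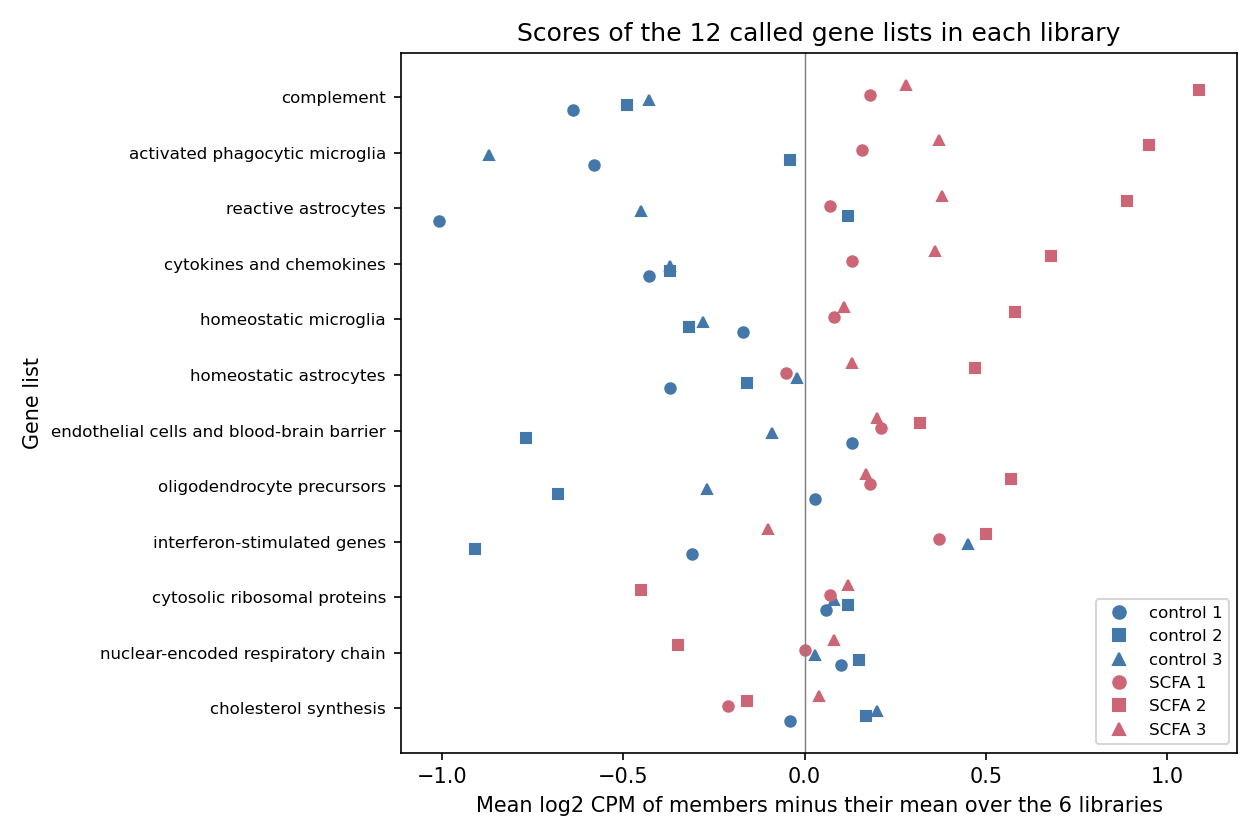
Score of each of the 12 called gene lists in each library, as the mean log2 CPM of the members minus their mean over the 6 libraries, controls in blue and SCFA in red. In complement the SCFA libraries scored 0.18, 1.09 and 0.28 and the controls -0.64, -0.49 and -0.43.

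Neuronal and synaptic lists were not called in the main test. Under the 20 alternatives, striatal neurons passed in 6, upper cortical layers in 4 and dendritic spine and axon plasticity in 1. The excitatory, inhibitory, presynaptic and postsynaptic lists passed in 0. Excitatory neurons had a median of 0.17 over 10 genes (adjusted p = 0.231) and inhibitory neurons of 0.16 over 9 (adjusted p = 0.588). Presynaptic genes had a median of 0.13 (adjusted p = 0.237) and postsynaptic genes of -0.02 (adjusted p = 0.711). Snap25 measured 273 ± 28.1 CPM in controls and 260 ± 22.3 with SCFA, and Syp, a synaptic vesicle protein gene, 532 ± 82.4 and 622 ± 120 (SD, n = 3 each). Bdnf, a neurotrophin gene, had a log2 fold change of 0.57 with an SE of 0.792. Myelinating oligodendrocytes (median 0.20, adjusted p = 0.826), pericytes (-0.02, adjusted p = 0.588), fibroblasts (-0.08, adjusted p = 0.588) and infiltrating monocytes (-0.06, adjusted p = 0.997) did not pass. Striatal neuron genes, which mark a region beneath the cortex, had a median fold of 2 (adjusted p = 0.173) that rested on SCFA 2, whose score was 1.76 against -0.78 to 0.40 elsewhere. Penk had 1895 counts in SCFA 2 and 242 to 360 in the others. Without SCFA 2 the median log2 fold change was -0.47. In 7 of the lists not called, the median, the mean and the direction of the test differed in sign (hippocampus and thalamus, glycolysis, hypoxia and angiogenesis, glial scar and extracellular matrix, choroid plexus and ependyma, heat shock and unfolded protein response, hormones and neuropeptides).

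Of the receptors that sense SCFA, Ffar2 had 5 counts in all 6 libraries together, Ffar3 had 1 and Hcar2 had 16, too few to compare. The transporter gene Slc16a1 measured 24.4 ± 5.08 CPM in controls and 43.1 ± 7.28 with SCFA, a log2 fold change of 0.82 (SE 0.223) that did not pass (adjusted p = 0.795). The list of SCFA receptors, transporters and metabolism was not called (median 0.08, adjusted p = 0.588). Of its 10 tested members, 1 passed in the higher direction adjusted over the list alone. Among histone deacetylases, enzymes that butyrate inhibits, Hdac1, Hdac2 and Hdac3 had log2 fold changes of 0.55, -0.40 and -0.26, and none passed. Of the microglial genes Aif1, Cx3cr1 and Cd68, the log2 fold changes were -0.39 (SE 0.343), 0.58 (SE 0.213) and 0.74 (SE 0.459). Trem2 had 11 counts in all and Dlg4 had 0, and neither could be compared.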

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

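The transcript rows and the comparison without control 2 and SCFA 2 were chosen after the data had been seen. The count of genes higher was 1 and of genes lower 9, and both were equal to that with DESeq2 size factors, upper-quartile scaling, the stricter filter and unsummed transcript rows. Without a filter 30 genes were higher and 25 lower, with DESeq2 16 and 21, and with limma-voom 0 and 0 (421 and 384 at an unadjusted p under 0.05). The unfiltered edgeR test gave Amy2a5 an adjusted p of 5.75e-146 against 0.0107 in the main test, at log2 fold changes of -8.838 and -8.847. A value that small from 3 libraries per group is not credible, so the 30 and 25 genes carry little weight. Total-count scaling gave 1 and 11, and its higher gene was C3, named here after its values were seen, in place of Laptm5. With the replicate number as a block, 10 genes were higher and 12 lower, and 13 lists were called. Same-numbered libraries did not deviate together (correlations -0.00206, 0.0101 and -0.00525), so no pairing by number was seen. A pairing that touches few genes could be missed by these correlations. Leaving out 1 library gave 0 to 8 genes higher, 0 to 13 lower and 5 to 16 lists. Without control 2 and SCFA 2, 14 genes were higher, 11 lower and 8 lists called. Among the 39 lists tested, 12 were called, 0 with an estimated correlation and 0 with fry (lowest adjusted p 0.405 and 0.106, with 4 and 6 of the 39 at an unadjusted p under 0.05), 13 with limma-voom and 14 from the DESeq2 statistics. Among the 12 called lists the lowest adjusted p with fry was 0.252. The 5 microglia, complement and astrocyte lists passed in 18 of 20 alternatives each, all but estimated correlation and fry. Those 18 all kept the preset correlation of 0.01, while the estimated correlations of the 5 lists were 0.164 to 0.449. The test of cytosolic ribosomal proteins turned from lower to higher without control 2 and SCFA 2, where the median was -0.00834 (adjusted p 0.932). The sign of 123 named genes changed in 23 comparisons, none with a call. The cause of these changes was not tested, except that fewer libraries or another filter alter which genes are tested. Genes with few counts, or with several transcripts whose shared reads may not have been counted, could be compared less well.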

Other observations

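The tests of pancreatic RNA, of depth, of SCFA 2 and of neurons were chosen only after the results had been seen, and those of GC content and length, of thinned counts and of the splits beforehand. Families of genes with a common symbol stem, a grouping also made afterwards, gave no call among the 75 families with at least 15 tested genes (camera). Genes with the symbol stem Rps had the smallest adjusted p, 0.0863, with a median log2 fold change of -0.11 and 32 of 42 genes below 0. Their score was lowest in SCFA 2 (-0.34), while SCFA 3 scored 0.09 and the controls 0.08 to 0.09. The 301 Zfp genes, most of them encoding zinc finger proteins, had a median of -0.10 (adjusted p = 0.115), with 184 below 0. Their groups overlapped too, with control 2 at -0.16 and SCFA 1 at 0.08. The 22 Cyp genes, which encode cytochrome P450 enzymes, had a median of 0.52 (adjusted p = 0.115), and each SCFA library scored above each control. Such a separation of 3 from 3 libraries, in either direction, arises by chance in 10% of cases, and the Kctd and Phf families also showed it. The Cox, Cd and Cep families had the same adjusted p as the Cyp genes. With an estimated correlation the adjusted p of the Cyp genes was 0.956 (camera).

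In this cortex series the exocrine pancreas list had 3550, 4007 and 508 counts in controls 1 to 3 and 49, 63 and 78 in SCFA 1 to 3, and its 31 genes include the 9 called ones that prompted it. A difference in depth is argued against, since the list's share of the total counts differed by 45.4 times. A candidate explanation is RNA from exocrine pancreas in the control libraries: of the 17 genes of the list outside the 9 called with at least 9 counts over the 6 libraries, 11 had each control above each SCFA library, and of all genes with 9 counts up to the highest total among those 17, 3.69% did. Other organs gave fewer counts, with 340 and 52 for liver, 535 and 177 for intestine (401 of them in control 1), 3 and 1 for islets, 55 and 96 for muscle, 3 and 16 for salivary gland and 1 and 4 for kidney. As shares of total counts, liver was 7 times and intestine 3.24 times higher in controls, while muscle, salivary gland and kidney were lower. Of the liver genes, Alb had 0 counts in controls, and Apoa1 had 154, all in control 1. Control 1 also held 105 of 107 control counts of Muc2 and all 67 of Sis, where SCFA 1 held 16 and 8. A joint lowering of the exocrine genes with SCFA would give the same 11 of 17 genes, so that count cannot separate the explanations. The 17 were listed with the gene results already seen, and Cel and Dmbt1 among them passed at an adjusted p under 0.1 (edgeR). They are thus not independent of the 9 called genes. The 17 also include Try4, Cela1 and Cela3b, from families in which the split of reads among copies is uncertain. Where pancreatic RNA would have come from, and an effect of SCFA on these genes in the cortex, stay open and untested.

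The rise of microglia, complement and astrocyte lists could have come from SCFA 2 alone, from fewer neurons or from a bias by GC content and length. The glial median exceeded that of the other non-neuronal genes (endothelial cells, oligodendrocyte precursors, pericytes, fibroblasts and myelinating oligodendrocytes) by 0.363 (95% interval over genes 0.227 to 0.668). Endothelial cells and oligodendrocyte precursors were themselves called higher. This difference cannot decide on fewer neurons, since the 5 glial lists were picked after they were called and the interval takes genes as independent. Excitatory and inhibitory neuron genes had a median of 0.163 (interval over genes -0.0561 to 0.299), so no fall of neuronal genes was seen. With the trend on GC content and transcript length removed, the median of the 61 glial genes was 0.565, as before. In a separate test with no trend removed, all 5 lists were still called without SCFA 2 at the preset correlation, each with a lower median. That test cannot exclude SCFA 2 as the main source, since the lists were picked after they were called. No estimated correlation was used without SCFA 2. An effect of SCFA on glia, the extent of the lesion and the piece of cortex taken stay open, and the lists lost their calls with an estimated correlation (adjusted p = 0.405).

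Control 2 detected fewer genes than the others, which fewer usable counts might explain. Thinned to its 5092272 counts outside the dominant row, each of the other 5 libraries still detected at least 14.5% more genes, which argues against that. Of genes picked after their values were seen, Mir6236 took 2.54% of the counts in control 2 (0.515% to 0.769% in the others), Lars2 1.92% (0.610% to 1.04%) and Cdr1 0.626% (1.16% to 2.41%). The quality of its RNA or a step of library preparation stays open, and no biological explanation was tested.

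The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene higher, 9 lower and 12 lists, and 1 of the 10 splits, the real one, reached each of these. The highest among the others was 0 genes in a direction and 7 lists.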
